A study of Mus musculus with 8 samples.

How the data were processed

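Single-cell RNA-seq was measured in mouse (CD1) cortex at embryonic day 16.5, in 4 samples from wild type littermates and 4 samples from brains electroporated in utero with a ShhN plasmid at embryonic day 13.5. In utero electroporation drives plasmid into progenitors lining the ventricle of the living embryo. ShhN is the signalling fragment of sonic hedgehog (SHH). Per the labels' protocols, cortices were dissected under a fluorescence stereoscope and dissociated with papain, and libraries were made with the 10x Genomics Chromium droplet system. The labels do not say whether the wild type littermates were electroporated with another plasmid.

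The deposited values are counts of unique molecular identifiers (UMIs) per gene and droplet barcode, with no normalization, in 1 matrix per group. Each matrix lists 27998 genes and 737280 barcodes, so empty droplets are included. Per the submitters' processing notes, Cell Ranger, StringTie, Seurat 3 and the mm10 build were used; their roles are not given in the sources used here. All barcodes of a matrix carry 1 suffix, so cells could not be traced to the 4 samples of a group, and each group was treated as 1 library. The matrices name their group only by control and experimental prefixes, which were matched to the wild type and ShhN titles. With 1 library per group there was no test between groups, and no difference has a replicate check.

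The following choices were made before the data were examined, except where stated. Cells were barcodes with total UMIs of at least 10% of the 99th percentile of the top 3000 barcodes of their library, at least 800 detected genes and at most 10% mitochondrial UMIs. The UMI threshold was 2333 in the wild type and 2291 in the ShhN library. Doublets were called per library with scrublet in scanpy 1.11.5 at an expected rate of 6% and removed. They made up 4.05% of 7216 wild type barcodes and 2.91% of 8317 ShhN barcodes.

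Counts per 10000 UMIs were log-transformed. Both libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with leidenalg 0.10.2 and python-igraph 0.11.9. SHH targets, SHH receptors and mediators, globins, mitochondrial genes, Xist and Y-linked genes were left out of the variable genes, so that the treatment readout did not define clusters. No batch correction was applied. The 31 clusters were named from 21 fixed marker lists. A name needed at least 3 markers detected in 10% of the cluster's cells and 1.5-fold above the other cells. It was withheld where other classes held more of the 10 leading genes than the named class. The scoring was adjusted after the clusters were seen. Where one of the next best classes held more of the leading genes, that class was taken, and a cluster led by S100a8 was left unnamed. This gave 25 named clusters. The names were rebuilt here and may differ from the authors' own.

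UMIs were summed per class and library and scaled to the class total as CPM. CPM carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95%. They cover counting error only, not differences between embryos, electroporations or libraries. A share of 0 is given with a limit of 3 cells over the total, which lies below the upper Clopper-Pearson bound. Where a gene had 0 UMIs in a library, the ratio was computed against a floor of 3 counts in that class and is a lower bound that leaves counting error aside. A gene passed the size rule with at least 50 UMIs over both libraries, a log2 ratio of at least 1 in size, and the interval bound nearest 0 at least 0.5 in size on the same side. Genes named were the 12 highest and 12 lowest past this rule in radial glia-like cells, ranked by that bound. In each other class with at least 100 cells in both libraries the 4 highest and 4 lowest were named, and over all cells the 5 highest and 5 lowest. The ranking left out globins, mitochondrial genes, Xist, Y-linked genes and gene models without a name. Members of 20 fixed gene lists could also be named. Some genes that meet these rules, and a share that rests on one of them, are not reported here. A list's median log2 ratio was set among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Lists with fewer than 3 measured members got no median.

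For shares of cells with a UMI, each cell was thinned to 4500 UMIs and shallower cells were left out. Endothelial-like and mural-like cells served as background. Free RNA was measured in barcodes with 1 to 50 UMIs. The share of cells with a Mki67 or Top2a UMI was added after the planned cycle thresholds proved close to saturation.

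Alternatives covered cell calling, doublets, clustering resolution and genes, clustering in the wild type library alone with ShhN cells assigned to their nearest wild type cells, scaling (TMM), equal weight per cell, subtraction of free RNA, thinning and count filters. Counts restricted to clusters 4 and 12, the interneuron class without cluster 20, cluster 17 counted among progenitors, and the Mki67 or Top2a measure were chosen after seeing the data.

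The ratio step was tested on simulated data with 200 genes changed by known amounts. Counts were Poisson draws from wild type proportions, without variation between cells, embryos or libraries, so the recovery covers counting error only. In radial glia-like cells 79% of the genes set to a log2 ratio of 1.5 and 82% of those set to 2.5 were recovered among 6683 genes run. In neurogenic intermediate progenitor-like cells the shares were 96% and 90% among 10272 genes, with the right sign in 100%. Gene coordinates came from GENCODE M21 on GRCm38 (mm10), matched by gene ID for 27645 of the 27998 genes. The marker Ccn2 was found only under its older symbol Ctgf. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.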

Results

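The study compared the cortex of wild type littermates with cortex that had received ShhN by in utero electroporation, at embryonic day 16.5, when cortical progenitors are making upper layer neurons. Per its title, it asks how SHH as an outside signal regulates the lineage progression of cortical neural stem cells. Each group's 4 samples were pooled in 1 library. The wild type library held 63760199 UMIs and the ShhN library 69470062, of which 72.9% and 82.5% lay in the 6924 and 8075 cells kept after doublet removal. Median depth was 6279 UMIs and 2400 genes per wild type cell, and 6683 UMIs and 2422 genes per ShhN cell. Globin transcripts, which come from blood, made up 8488 CPM of the wild type and 4413 CPM of the ShhN cells.

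Shh itself (chromosome 5, 28456815 to 28467256, GRCm38) was seen in the ShhN library alone of these 2 libraries. No UMI was found in 6924 wild type cells, with a limit of 0.0433% by the rule of 3 cells, which limits cells with a UMI and not cells that express the gene. The ShhN library held 5910 Shh UMIs, or 103 CPM [100, 106], 1597-fold above a wild type floor of 3 counts, with a lower counting bound of 1298-fold. Of its 8075 cells, 587 (7.27% [6.71, 7.86]) had a Shh UMI and 334 had at least 3. Expression was uneven, since 71 cells with at least 20 UMIs carried 61.3% of all Shh UMIs. The share of cells with a Shh UMI was 11.2% among upper layer neuron-like, 8.65% among migrating neuron-like and 5.79% among neurogenic intermediate progenitor-like cells. It was 3.56% among radial glia-like and 3.33% among GABAergic interneuron-like cells. These UMIs do not tell plasmid from endogenous transcripts. Shh was also found in ShhN barcodes with 1 to 50 UMIs, at 116 CPM, so part of the cells with a single UMI can be free RNA. Of the 36 endothelial-like and mural-like ShhN cells, 1 had a Shh UMI.

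Most measured genes that SHH signalling induces were higher in the ShhN library when all cells were summed. Over all cells, Gli1 (chromosome 10, 127329882 to 127341974), the transcription factor that reports pathway activity, had 4 wild type and 193 ShhN UMIs, a log2 ratio of 5.29 [3.91, 7.18]. Ptch1 (chromosome 13, 63508328 to 63573598), the SHH receptor and its feedback inhibitor, had 249 and 1931 UMIs (2.65 [2.46, 2.85]). Hhip (chromosome 8, 79965851 to 80058006), which binds and sequesters SHH, had 3 and 381 UMIs (6.69 [5.13, 8.97]). Nkx2-2, a ventral homeobox gene, was higher by 5.34 [3.45, 8.41]. Ccnd2, the cyclin of the G1 phase, was higher by 1.95 [1.91, 1.99]. In all, 6 of the 9 measured SHH targets passed the size rule, each higher, with a list median of 2.12 that lay above 100% of matched random lists. Ccnd1 (0.78), Mycn (0.14) and Bcl2 (-0.20) did not pass it. Of the 9 measured receptors and mediators, Shh and Gli2 (1.26 [0.94, 1.59]) passed the rule, both higher, and the list median was 0.05 at the 92.4th percentile.

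Class shares were compared next, to ask which kinds of cells each library held. Radial glia-like cells, the stem cells of the cortex, made up 2.54% [2.18, 2.94] of wild type and 3.13% [2.76, 3.54] of ShhN cells. Neurogenic intermediate progenitor-like cells, named after the Eomes-expressing daughters that make excitatory neurons, made up 15.8% [14.96, 16.7] and 25.02% [24.1, 26.0]. This class joins clusters that went in opposite directions, and its rise does not show more Eomes-led cells. Its clusters 4 and 12, with Eomes among their leading genes, held 12.5% and 6.69%. Glial or olfactory bulb intermediate progenitor-like cells, led by Olig1, Olig2 and S phase genes such as Mcm3, made up 0.708% [0.524, 0.935] and 4.30% [3.87, 4.76], a ratio of 6.07. In most of them no Olig UMI was seen: at equal depth Olig1 or Olig2 was seen in 19.1% of the wild type and 24.8% of the ShhN cells of this class, and Eomes in 72.3% and 53.8% (18.4% and 25.6%, and 75.5% and 58.2%, before thinning). GABAergic interneuron-like cells, named after neurons that migrate into the cortex from the ventral forebrain, made up 11.4% [10.6, 12.2] and 5.21% [4.74, 5.72], a ratio of 0.458. The class includes cluster 20, with 13 wild type and 143 ShhN cells, whose origin is left open below. Upper layer neuron-like cells were 27.0% and 21.6%, migrating neuron-like cells 19.1% and 20.6%, and deep layer neuron-like cells 13.53% and 13.2%. Cajal-Retzius-like cells, the Reln-secreting cells of the cortical surface, were 1.01% and 0.372%. Unnamed clusters held 7.89% and 5.91%.

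**Figure D1:**
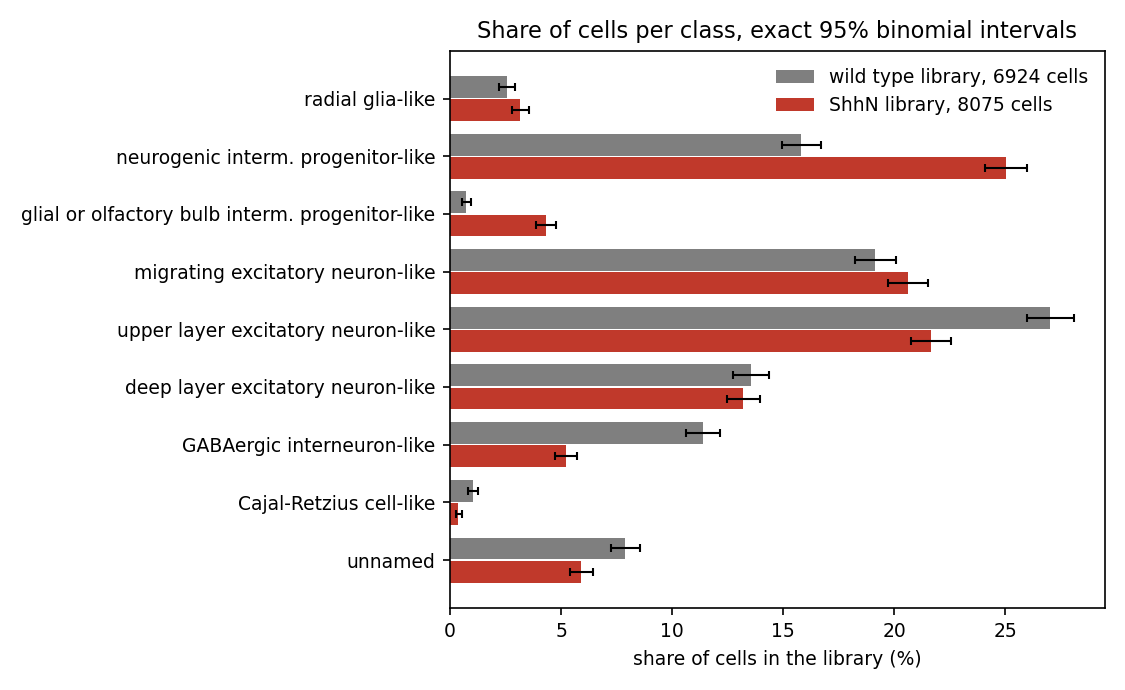
Share of cells (%, horizontal axis) in each class for the wild type library (grey, 6924 cells) and the ShhN library (red, 8075 cells), with exact 95% binomial intervals as error bars. The intervals of the 2 libraries do not overlap for neurogenic intermediate progenitor-like cells (15.8% and 25.02%), glial or olfactory bulb intermediate progenitor-like cells (0.708% and 4.30%) GABAergic interneuron-like cells (11.4% and 5.21%), upper layer neuron-like cells (27.0% and 21.6%), Cajal-Retzius-like cells (1.01% and 0.372%) and unnamed cells (7.89% and 5.91%).

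Within classes the libraries filled different clusters, and a cluster mostly from 1 library may be that library and not a cell type. Neurogenic intermediate progenitor-like cells of the wild type lay mainly in clusters 4 and 12, with 12.5% of wild type and 6.69% of ShhN cells. Clusters 3, 10 and 16 of the same class held 3.29% and 18.3%, and clusters 10 and 16 among them were led by mitotic genes such as Top2a, Nusap1 and Cenpa. Cluster 3 was 88.4% ShhN cells, with 3 of the 12 class markers up and Eomes not among its leading genes. Clusters 10 and 16 had 10 and 9 of the 12 markers up, but 0 among their 10 leading genes. Among interneuron-like cells, clusters 6 (Sst, Lhx6) and 19 (Htr3a, Npas1) held 11.2% of wild type and 3.44% of ShhN cells. Cluster 20, led by Dlx6os1, Sp9 and Ccnd2, held 0.188% and 1.77%. The unnamed cluster 17, led by Olig1, Top2a, Sp9 and Dlx2, held 0.202% and 2.40%, and the unnamed cluster 11 of Crym and Nrp2 held 4.74% and 1.44%. Clustering without the genes past the size rule in radial glia-like cells gave a ratio of 2.81 for the neurogenic and 11.2 for the glial or olfactory bulb class. Clusters drawn in the wild type library alone turned the neurogenic ratio to 0.622, from 4.30% to 2.67%, while the glial or olfactory bulb class then took 2.40% of wild type and 13.7% of ShhN cells. Unnamed clusters held 30.2% and 28.0% in that setting. Clustering without cycle genes left no cluster of the glial or olfactory bulb class in either library, so its share depends on those genes being used. The upper layer difference was absent in several settings, with ratios of 0.996 at resolution 0.5, 0.9997 with wild type clusters and 1.12 with at most 5% mitochondrial UMIs.

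**Figure D2:**
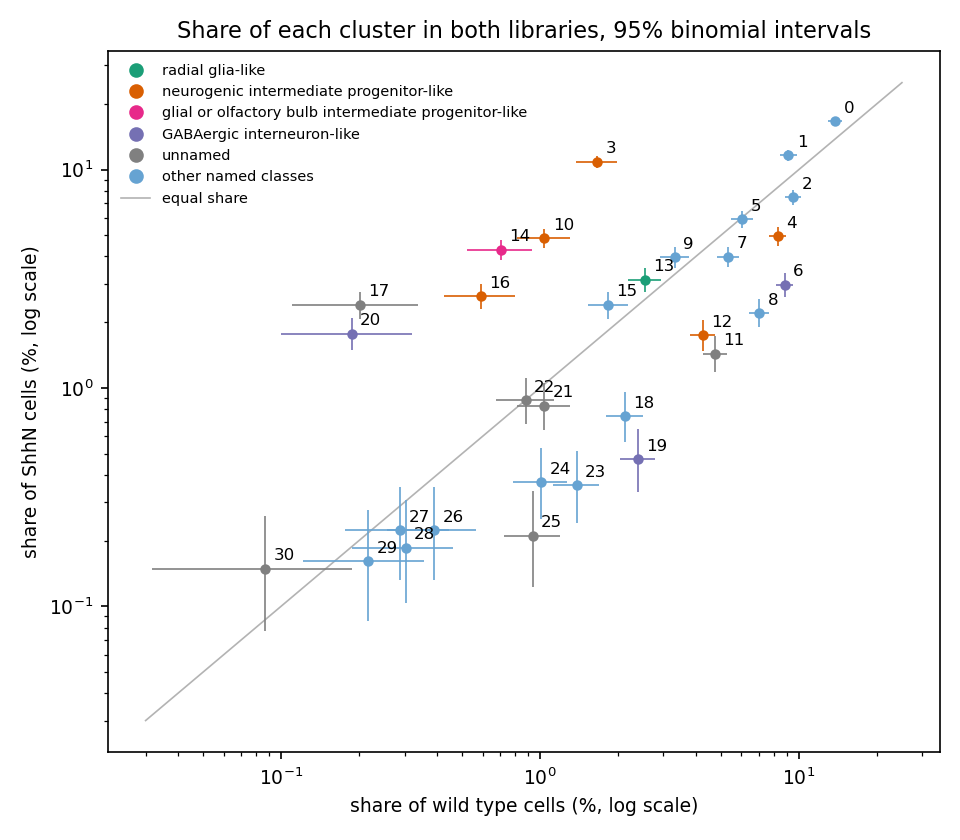
Share of wild type cells (%, horizontal log axis) against share of ShhN cells (%, vertical log axis) for each numbered cluster, coloured by class, with exact 95% binomial intervals and a grey line of equal share. Clusters 3, 10, 14, 16, 17 and 20 lie far above the line and clusters 6, 8, 11, 18, 19, 23, 24 and 25 far below it.

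In radial glia-like cells, 176 in the wild type and 253 in the ShhN library, the SHH targets Ptch1, Hhip and Ccnd1 and the growth factor genes Igf1 and Fgf15 were higher in the ShhN library, while Eomes and Mfap4 of the neurogenic program and Hopx and Tnc of the radial glia list were lower. Ptch1 had 14 and 188 UMIs (3.41 [2.62, 4.30]). Hhip had 0 and 65 UMIs, at least 17.1-fold higher. Igf1 (chromosome 10, 87858265 to 87937042), a secreted growth factor, had 0 and 91 UMIs, at least 23.9-fold higher. Fgf15 (chromosome 7, 144896531 to 144900953), an FGF ligand of embryonic progenitors, had 1 and 92 UMIs (6.18 [3.67, 11.50]). Ccnd1, the cyclin that drives entry into S phase, was higher by 1.10 [0.68, 1.53], whereas Ccnd2 (0.41) was not past the rule. Gli1 had 3 and 39 UMIs (3.36 [1.70, 5.70]), below the 50 UMIs the rule asks for.

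The rule passed 38 genes as higher and 34 as lower of 6796 measured in this class. Beyond those above, the highest were Entpd2, an ATP-degrading enzyme of neural stem cells (3.92), Mro (3.27), Tbc1d22a (2.81), Nell2 (2.34), Cmtm8 (2.24), the immediate early gene Egr1 (2.19), Fgfbp3, which releases FGFs from the matrix (2.001 [1.79, 2.22]), and Chic2 (1.69). The lowest were Alas2 (-2.63), Htra1, a secreted protease (-2.51 [-3.17, -1.89]), the lipid synthesis regulator Thrsp (-2.04), Btbd17 (-1.90), the neurotrophin receptor Ntrk3 (-1.81), Bach2 (-1.68) and Mfap4 (-1.63). They went on with Bcan, a matrix proteoglycan of glia (-1.51), Hopx, a marker of outer radial glia (-1.48 [-1.96, -1.01]), the metallothionein Mt2 (-1.36) and Abracl (-1.16). Alas2 belongs to red blood cells, and free RNA of barcodes with 1 to 50 UMIs held it at 34.2 CPM in the wild type and 15.9 CPM in the ShhN library.

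Among SHH targets in radial glia-like cells, 3 of 6 measured members were higher and none lower, with a median of 0.75 at the 100th percentile. Cells thinned to equal depth gave 0.44. None of 6 measured SHH receptors and mediators passed the rule (median 0.09, percentile 83.0). Of the glial and olfactory bulb intermediate progenitor list, 2 of 6 measured genes were higher, Fgfbp3 and Olig2 (9 and 42 UMIs, 1.88 [0.82, 3.11]), and the median was 0.45 at percentile 99.9. The ventral patterning list had 1 of 3 measured genes higher, again Olig2 (median 0.33, percentile 86.7). None of 4 measured olfactory bulb interneuron genes passed the rule (median -0.05, percentile 36.9).

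Of the excitatory neurogenic program, 2 of 8 measured genes were lower and none higher, with a median of -0.61 below all matched random lists. They were Eomes, the regulator of intermediate progenitors (-1.03 [-1.32, -0.73]), and Mfap4, and the proneural gene Neurog2 stood at -0.86. None of 8 dorsal patterning genes passed the rule, but their median was -0.32 at percentile 0.030, with Lhx2 at -0.67, Emx2 at -0.65 and Emx1 at -0.48. Of 15 radial glia and stem cell genes, Hopx and Tnc (-1.15), a matrix protein of outer radial glia, were lower, Hes1, a Notch effector, stood at 0.84, and the median was 0.10 at percentile 97.1. Among 11 astrocyte genes, Sparcl1 was higher (1.11 [0.63, 1.61]) and the median was -0.39 at percentile 0.010. Among 11 Notch pathway genes, the ligand Jag1 was higher (1.41 [0.52, 2.38]), with a median of -0.29 at percentile 0.325. No BMP and WNT response gene of 6 measured (median -0.28, percentile 1.47) and no FGF and ERK response gene of 8 (median -0.21, percentile 10.1) passed the rule.

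**Figure D3:**
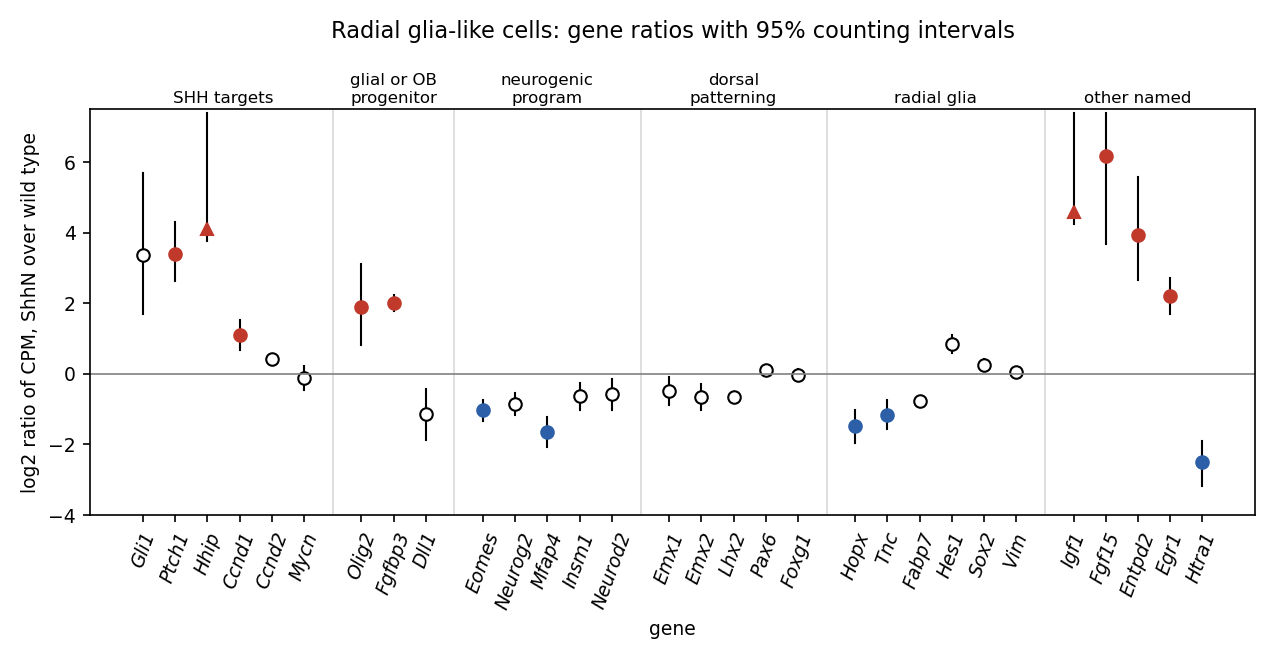
Log2 ratio of CPM, ShhN over wild type (vertical axis), for named genes and list members (horizontal axis) in radial glia-like cells, with 95% counting intervals as lines that stop at the top of the axis where they run past it. Red points are past the size rule and higher, blue points past it and lower, open points not past it, and triangles lower bounds for genes with 0 wild type UMIs; Ptch1 lies at 3.41 and Htra1 at -2.51.

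The S phase list had a median of 0.56 at the 100th percentile in radial glia-like cells with none of 33 measured genes past the rule. Thinning to equal depth gave a median of 0.23 and finer clusters 0.15. The G2 and M phase list had a median of 0.01 (percentile 63.0, 0 of 49 past the rule). Of 10 stress genes, Egr1 alone was past the rule, with a median of 0.25 at percentile 99.95. The median of 3 measured p53 response genes was 0.21 (percentile 86.0). Of 4 erythroid genes, Hba-a1 (-1.25), Hbb-bt (-2.42) and Alas2 were lower. Fewer than 3 oligodendrocyte, interferon or microglia genes were measured in this class. The count of genes past the rule depended on the filter, with 8 higher and 9 lower at a minimum of 200 UMIs, 72 higher and 88 lower without a minimum, and 13 higher in thinned cells.

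Transcripts of the glial progenitor genes were then counted per cell, to ask how many progenitors carried them at equal depth. After thinning, 964 wild type and 2249 ShhN progenitors remained, and 356 and 371 shallower ones were left out. Olig1 or Olig2, the regulators of oligodendrocyte fate, were seen in 1.76% [1.03, 2.81] and 6.003% [5.06, 7.07] of them (1.89% and 6.76% before thinning). Gsx2, a homeobox gene of ventral progenitors, was seen in 0.311% and 2.71% (0.303% and 3.82%), and Egfr, a receptor of late progenitors, in 1.14% and 3.07%. Eomes was seen in 64.3% [61.2, 67.3] and 45.7% [43.6, 47.7] (63.9% and 49.7%), and Neurog2 in 49.2% and 39.4% (50.1% and 44.5%). Which cells count as progenitors rests on the clustering, so these shares do not show a change over all cells. In radial glia-like cells alone, Olig1 or Olig2 was seen in 1 of 149 wild type and 21 of 207 ShhN cells, a ratio of 15.1, and before thinning in 3 of 176 and 30 of 253, a ratio of 6.96.

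In the endothelial-like and mural-like background, 0 of 35 wild type and 1 of 32 ShhN cells had an Olig1 or Olig2 UMI, with a wild type limit of 8.57% by the rule of 3 cells. No background cell had a Gsx2 UMI, but Egfr was seen in 2.86% and 3.12% of background cells (1 cell in each library), no less than in the progenitors, so no difference is read from its share. Median depth was 5365 and 5912.5 UMIs in the progenitors and 7114 and 7589 UMIs in the background cells. The background is too small to set a level under the wild type shares.

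Cell cycle genes set the libraries apart more than any other fixed list except SHH targets, by the median over all cells. There, 39 of 51 measured G2 and M phase genes and 22 of 42 S phase genes were higher and none lower, with medians of 1.58 and 1.08. Mki67 or Top2a, markers of dividing cells, were seen in 4.75% [4.19, 5.36] of 5260 wild type and 14.8% [14.02, 15.7] of 7018 ShhN cells deep enough to be thinned, with 1664 and 1057 left out (5.36% and 16.1% before thinning). Among neurogenic intermediate progenitor-like cells the shares were 12.6% [10.4, 15.2] and 29.4% [27.3, 31.7]. Among radial glia-like cells they were 35.6% and 38.2%, with overlapping intervals. In the background they were 5 of 35 and 4 of 32 cells. Of these, 5 of 20 and 3 of 17 were endothelial-like, and 0 of 15 and 1 of 15 mural-like cells. The 2 kinds of cell are too few and too unlike to set a noise level for these markers. Free RNA held Top2a at 12.3 and 85.6 CPM. The planned threshold of 3 G2 and M phase UMIs was met by 91.3% and 95.2% of progenitors and by 82.9% and 68.8% of background cells. That of 3 S phase UMIs was met by 75.3% and 82.3% of progenitors and by 57.1% and 81.2% of background cells.

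In neurogenic intermediate progenitor-like cells, 257 genes were past the rule as higher and 188 as lower of 10245 measured. Named genes were Shh, Ptch1 (10 and 427 UMIs, 4.35 [3.46, 5.42]), Hhip (0 and 77 UMIs, at least 12.3-fold) and the synaptotagmin Syt13 (5.43 [2.91, 10.75]) as higher, and Ttr (-5.95 [-9.03, -4.03]), Shisa9 (-2.71), Luzp2 (-2.61) and Dmrta2os (-2.78) as lower. Gli1 had 0 and 54 UMIs, at least 8.61-fold higher. Of 7 SHH targets 3 were higher (median 0.89), and of 51 G2 and M phase and 42 S phase genes 38 and 16 were higher (medians 1.21 and 0.82). Hes1, which holds progenitors undifferentiated, was higher by 3.68 [2.91, 4.56], while the Notch feedback gene Nrarp (-1.77) and Gli3, the repressor of SHH targets (-1.08), were lower. Of 13 neurogenic genes, Neurod4 (-1.23) and Mfap4 (-1.13) were lower (median -0.26), and the median of 9 dorsal patterning genes was -0.52 with none past the rule. In clusters 4 and 12 alone, 15 genes were higher and 44 lower, and the G2 and M phase median was 0.27, in a smaller set of cells chosen after the clusters were seen. TMM scaling shifted the log2 ratios of this class by 0.108, with 304 genes then higher and 136 lower.

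Glial or olfactory bulb intermediate progenitor-like cells numbered 49 in the wild type, under the 100 set for the size rule counts. Their interneuron fate genes Dlx1 (1 and 118 UMIs, 4.18 [1.67, 9.49]) and Dlx2 (2 and 186 UMIs, 3.83 [1.961, 6.89]) were higher in the ShhN library, and Emx1, a gene of the dorsal cortex, was lower (-1.004 [-1.46, -0.53]). The median of 9 olfactory bulb interneuron genes was 1.03 and of 8 dorsal genes -0.58.

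In the excitatory neuron classes fewer genes were past the rule than in neurogenic intermediate progenitor-like cells as a whole. Clusters 4 and 12 of that class alone, counted above, had fewer than migrating or upper layer neuron-like cells and more than deep layer neuron-like cells. The comparison of whole classes therefore does not separate gene differences from a different mix of clusters. Migrating neuron-like cells had 37 genes higher and 46 lower of 9898, upper layer neuron-like cells 32 and 97 of 10440, and deep layer neuron-like cells 5 and 16 of 9811. TMM scaling gave 49 and 39 in migrating and, with a shift of 0.107, 8 and 8 in deep layer neuron-like cells. Shh itself was among the highest in each. Cdk6, a kinase of the G1 phase, was higher in migrating (2.21 [1.86, 2.57]), upper layer (3.63 [2.82, 4.57]) and deep layer neuron-like cells (3.07 [2.09, 4.25]). Others named as higher were Hes1 (3.22) and Btbd11 (1.92) in migrating, Spc25 (2.17) and Fam84a (1.36) in upper layer, and Crip1 (1.80) and Gadd45g (1.41) in deep layer neuron-like cells. Hes1 (4 and 50 UMIs) and Spc25 (11 and 49 UMIs) rest on few counts, and Spc25 is a leading gene of the dividing cluster 10. Their levels in free RNA were not looked up, so part of these values can be free RNA. Lower were Grp (-3.07), Luzp2 (-1.93) and the Ephrin receptor Ephb1 (-1.61) in migrating, and Fam19a1 (-3.33), the semaphorin receptor Nrp2 (-3.04) and Trps1 (-2.83) in upper layer neuron-like cells. Fam19a1 is also a leading gene of cluster 8, which held 7.02% of wild type and 2.20% of ShhN cells; how much of its value comes from that was not tested. In deep layer neuron-like cells Nrp2 (-2.13), the activity-regulated gene Npas4 (-1.32) and Nr4a2 (-1.21) were lower. The median of the stress genes was -0.59 in deep layer and -0.27 in upper layer, but 0.11 in migrating neuron-like cells. Ptch1 was higher in migrating neuron-like cells (2.70 and 9.92 CPM, 1.88). Free RNA held it at 8.55 CPM in the wild type and 31.0 CPM in the ShhN library, a similar ratio. Part of this value can therefore come from free RNA, and how large a part was not tested. No SHH target passed the rule in upper or deep layer neuron-like cells. Ttr, a choroid plexus transcript, was lower in all 3 classes, and free RNA held it at 57.9 CPM in the wild type and at 0 of 1192277 UMIs in the ShhN library.

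GABAergic interneuron-like cells had 182 genes higher and 48 lower of 7652. The named genes were Cdk6 (3 and 227 UMIs, 6.85 [5.29, 9.14]), Ccnd2 (5.26), the replication genes Mcm3 (2 and 88 UMIs, 6.07 [4.17, 9.14]) and Clspn (1 and 68 UMIs, 6.70 [4.17, 12.02]) as higher, and Id3 (-2.49), Adamtsl1 (-2.48), Igf1 (-1.92) and Neb (-1.57) as lower. Of 31 S phase genes 24 were higher (median 1.79), and of 22 G2 and M phase genes 13 (median 2.01). Without cluster 20, 21 genes were higher and 19 lower, and the medians were -0.05 and 0.01.

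Over all cells, 371 genes were higher and 242 lower of 13032 measured. The highest were Shh, the neutrophil genes S100a8 (0 and 3801 UMIs), S100a9 (0 and 2563), Retnlg and Stfa3, and the lowest were Ttr (418 and 2 UMIs, -8.01 [-11.06, -6.15]), Spp1 (211 and 3 UMIs), Flnc (-3.45), Grp (-3.10) and Prrx2 (-2.97). Of S100a8, 3664 UMIs lay in 12 ShhN cells of cluster 30, and of Spp1, 205 lay in 6 wild type cells of that cluster. Of 10 glial and olfactory bulb intermediate progenitor genes 4 were higher, namely Gsx2 (4.11), Egfr (2.24), Olig2 (1.956) and Olig1 (1.49), with a median of 0.77. The oligodendrocyte list had 4 of 10 higher. They were Olig1 and Olig2 again, Nkx2-2, counted above as an SHH target, and Pdgfra, the receptor of oligodendrocyte precursors (2.79 [2.06, 3.61]). Pcdh15 (-1.69) and Lhfpl3 (-1.24) of this list were lower, and its median was 0.73. Of 15 olfactory bulb interneuron genes, Gsx2 was higher and Gad1, which makes GABA, lower (-1.03), with a median of -0.0089. Of 9 ventral patterning genes 3 were higher and Lhx6, a regulator of migrating interneurons, was lower (-1.59 [-1.75, -1.43]). Among 6 interferon genes Ifi27 (2.002) and Bst2 (1.04) were higher, and among 11 microglia genes P2ry12 (-1.74) was lower, with medians of 0.84 and 0.20.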

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

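These free RNA levels were looked up after the counts of the same genes in cells had been seen. In the ShhN library, barcodes with 1 to 50 UMIs held Shh at 115.7 CPM, S100a8 at 57.0 CPM and S100a9 at 35.2 CPM. The same barcodes of the wild type library held them at 0, 0.950 and 1.90 CPM. Shh stood at 103 CPM in the ShhN cells, close to its level outside them, and so a single Shh UMI does not mark a cell as electroporated.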

How the results depend on the processing

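The restriction to clusters 4 and 12, the interneuron class without cluster 20, cluster 17 counted among progenitors, and Mki67 or Top2a as the cycle measure were chosen only after the results were seen. No paired analysis was possible because each matrix pools the 4 samples of its group and no cell can be traced to a sample. Leaving out replicates was not possible for the same reason. The glial or olfactory bulb class had no cluster when cycle genes were left out of clustering. Over 72 results and 24 settings, 817 values were obtained: 589 were counted as the same, 207 as moved and 21 as changed in direction. A value counted as the same was not necessarily equal to the main value, and the size of change allowed is not given here. Among the 16 results that answer the study's question, 126 values were counted as the same, 55 as moved and 1 as changed in direction. Except where stated, the cause was not tested.

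The share of neurogenic intermediate progenitor-like cells had a ratio of 1.58, and clusters drawn in the wild type library alone turned it to 0.622. In that setting the class held only 298 wild type and 216 ShhN cells. The glial or olfactory bulb class then held 2.40% and 13.7%, and unnamed clusters 30.2% and 28.0%, so cells had changed class. The neurogenic ratio was 1.30 at resolution 0.5, 1.97 at resolution 2, 3.10 with 4000 variable genes, 2.81 without the genes past the size rule, 1.99 without cycle genes, 2.13 with at least 1500 genes and 2.60 with doublets kept. The ratio of 6.07 for the glial or olfactory bulb class became 11.7 at resolution 2, 11.2 without the genes past the size rule, 12.5 with at most 5% mitochondrial UMIs and 8.97 with at least 500 genes and no UMI threshold. The ratio of 0.458 for interneuron-like cells became 0.681 without cycle genes, 0.379 with wild type clusters, 0.531 with doublets kept, 0.379 with at least 500 genes and no UMI threshold, and 0.308 without cluster 20. That of 1.23 for radial glia-like cells became 1.57 with at least 500 genes and no UMI threshold.

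In radial glia-like cells, 38 genes were past the rule as higher and 34 as lower. Subtracting free RNA gave 58 and 53, no low count filter 72 and 88, a minimum of 200 UMIs 8 and 9, and thinned cells 13 higher. The SHH target median of 0.75 was 0.44 with thinned cells and 0.41 at 200 UMIs. The neurogenic median of -0.61 was -0.84 with free RNA subtracted and -0.86 without the filter. The S phase median of 0.56 was 0.36 with equal weight per cell, 0.23 with thinned cells, 0.15 at resolution 2, 0.33 with wild type clusters, 0.28 with at least 1500 genes and 0.37 with at most 5% mitochondrial UMIs. The stress median of 0.25 was -0.0015 with at least 500 genes and no UMI threshold.

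In neurogenic intermediate progenitor-like cells, 257 genes were higher and 188 lower. Thinned cells gave 168 higher, wild type clusters 69 and 36, doublets kept 128 higher, clusters 4 and 12 alone 15 and 44, no low count filter 300 lower and a minimum of 200 UMIs 78 lower. The G2 and M phase median of 1.21 was 1.32 with TMM, 1.33 with equal weight per cell, 1.07 with thinned cells, 1.45 at resolution 0.5, 0.96 at resolution 2 and 0.31 with wild type clusters. It was 0.83 with at least 1500 genes, 1.06 with at most 5% mitochondrial UMIs, 0.56 with doublets kept and 0.27 in clusters 4 and 12, where the neurogenic median of -0.26 became 0.0093. The ratio of cycling progenitors, 1.09 for S phase and 1.04 for G2 and M phase, was 1.25 and 1.15 at 5 UMIs, and 1.86 by Mki67 or Top2a. Ptch1 in radial glia-like cells (3.41) stayed within its main interval of [2.62, 4.30] in every setting run.

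Migrating neuron-like cells changed direction most often. Their share ratio of 1.08 became 0.845 with 4000 variable genes, 0.497 with SHH genes kept in clustering, 0.972 without the genes past the size rule, 0.910 with at least 1500 genes, 0.578 with at most 5% mitochondrial UMIs and 0.911 with doublets kept. Their G2 and M phase median of 0.12 became -0.28 with free RNA subtracted and -0.00085 with at most 5% mitochondrial UMIs. Their S phase median of -0.09 became 0.042 at resolution 0.5, 0.32 with wild type clusters and 0.064 with doublets kept. Their neurogenic median of 0.20 became -0.066 with wild type clusters, -0.24 with at most 5% mitochondrial UMIs and -0.0080 with at least 500 genes and no UMI threshold. The upper layer share ratio of 0.801 moved towards or past 1 in every setting run, to 1.01 with 4000 variable genes, 1.12 with at most 5% mitochondrial UMIs, 0.996 at resolutions 0.5 and 2, 0.9997 with wild type clusters, 0.972 with doublets kept, 0.957 with at least 500 genes and no UMI threshold, likewise 0.957 without the genes past the size rule, 0.891 with SHH genes kept, 0.880 with at least 1500 genes and 0.868 without cycle genes. In interneuron-like cells the neurogenic median of 1.71 became -0.11 with doublets kept, and the S phase median of 1.79 became -0.053 without cluster 20.

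Counts of genes past the rule in the other classes ranged, over the settings in which they were counted, from 18 to 67 higher and 12 to 97 lower in migrating, 13 to 50 higher and 39 to 158 lower in upper layer, and 2 to 16 higher and 8 to 35 lower in deep layer neuron-like cells. In interneuron-like cells they ranged from 21 to 408 higher and 17 to 144 lower, and over all cells 140 genes were lower at 200 UMIs and 155 with thinned cells.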

Other observations

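Of the tests below, those of striatal genes, free RNA and shallow cells were written before their results were seen, and the other tests were chosen after the results were seen. Cdk6, the kinase that pairs with D cyclins, was higher in each neuron and progenitor class with at least 100 cells in both libraries. It stood at 91.4 CPM in wild type and 235 CPM in ShhN radial glia-like cells, at 148 and 335 CPM in neurogenic intermediate progenitor-like cells, at 9.68 and 44.7 CPM in migrating and at 0.919 and 11.4 CPM in upper layer neuron-like cells. In endothelial-like cells (4 and 4 UMIs) and mural-like cells (17 and 11 UMIs) the counts of Cdk6 are too few to tell a difference from none. The level of Cdk6 in free RNA was not looked up, so part of the low values in neurons can be free RNA. In interneuron-like cells (3 and 227 UMIs) the sum includes cluster 20, with 13 wild type and 143 ShhN cells.

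Ptch1 was also seen in cells without a Shh UMI, and free RNA of the ShhN library held it at 31.0 CPM [21.9, 42.8], so part of it there can be free RNA. Over all ShhN cells it stood at 29.5 CPM in the 334 cells with at least 3 Shh UMIs and at 33.0 CPM in the 7488 cells without one, a log2 ratio of -0.16 [-0.51, 0.17], against 5.36 CPM in the wild type. That sum mixes classes of different Ptch1 levels, and within classes the ratio was 0.74 [-0.08, 1.46] in neurogenic intermediate progenitor-like, 0.82 [-0.82, 2.07] in radial glia-like (3 cells with Shh) and -0.55 [-1.79, 0.47] in upper layer neuron-like cells. Radial glia-like ShhN cells without Shh held Ptch1 at 101 CPM, against 9.76 CPM in wild type radial glia-like cells. Within neurogenic intermediate progenitor-like cells, Ccnd1 stood at 79.3 CPM in 49 cells with at least 3 Shh UMIs and at 37.4 CPM in 1903 cells without (1.08 [0.44, 1.66]), whereas over all cells its ratio was -0.48 [-0.85, -0.13], in upper layer neuron-like cells -0.78 [-1.75, 0.05] and in radial glia-like cells 1.39 [0.06, 2.47] (3 cells with Shh). These cells were chosen by their Shh counts and not set to equal depth.

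Clusters 14, 17 and 20, with Olig1, Olig2 or Dlx2 among their leading genes, together held 1.10% of wild type and 8.47% of ShhN cells, though in cluster 14 the other leading genes are S phase genes and Olig1 or Olig2 was seen in 24.8% and Eomes in 53.8% of its ShhN cells. They may hold cortical progenitors turned by SHH towards glial and olfactory bulb fates, or ganglionic eminence tissue in the ShhN dissection, or free RNA. The bound set beforehand against that tissue, a median log2 ratio of striatal genes under 0.5, was met at 0.11 (6 of 10 measured), but the test was judged afterwards to leave the question open, since members went from -0.59 to 4.22 for Isl1 (3 and 69 UMIs [2.61, 6.53]) and cortex itself expresses Ebf1 (437 and 535 UMIs), 1 of 3 members with at least 50 UMIs in wild type cells. Cluster 14 held the cortical gene Emx1 at 69.3 CPM [59.2, 80.6] in ShhN cells, against 4.91 CPM in the interneurons of cluster 6, which goes against a ventral origin of the whole cluster but leaves the origin of its Olig2 cells open, since its wild type cells held 139 CPM and clusters 17 and 20 held 12.7 and 9.87 CPM. Olig2 stood at 12.6 CPM in ShhN free RNA, close to the 12.3 CPM in wild type free RNA, and at 137 CPM in ShhN cells of clusters 14 and 17. This goes against free RNA as the source in those clusters. They have Olig2 among their leading genes, however, so a high level there was likely beforehand. The test does not cover cluster 20 (3.70 CPM).

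Interneurons of clusters 6 and 19 made up 11.2% of wild type and 3.44% of ShhN cells, possibly through dilution by added progenitors, loss of shallow cells, or a different extent of cortex dissected. Per deep layer neuron-like cell their number was 0.827 and 0.261, a log2 ratio of -1.66 [-1.90, -1.43], which goes against dilution. Lowering the gene minimum to 500 and dropping the UMI threshold together gave a log2 share ratio of -1.40 for the class. This goes against loss of shallow cells at the calling thresholds, but it cannot show cells lost before calling. Shallow clusters of excitatory neurons were also smaller in the ShhN library. Cluster 18 (median 2906 UMIs) held 2.12% of wild type and 0.743% of ShhN cells, and cluster 23 (3727 UMIs) 1.39% and 0.359%. The shallow unnamed cluster 22 (2941.5 UMIs) held 0.881% and 0.879%. Of 15 medial pallium genes 12 were measured and none was above 0, with a median of -0.89 (Nrp2 -1.89, Dmrt3 -1.68, Lhx9 -1.44, Rspo2 -1.41), as a dissection with less medial cortex would give. The test cannot tell such a dissection from an effect of ShhN on these genes, and it does not measure interneurons. Dorsal patterning genes, a list that shares Lhx9, Wnt8b and Dmrt3 with this one, were lower within several classes too, but not in all. Their median was -0.32 in radial glia-like, -0.52 in neurogenic intermediate progenitor-like, -0.45 in migrating and -0.31 in upper layer neuron-like cells, with none past the rule. In deep layer neuron-like cells it was -0.16 at percentile 19.4. In GABAergic interneuron-like cells, a sum that includes cluster 20, it was 0.84, with 2 of 4 measured genes higher. The medial pallium list was drawn up after Nrp2, Lhx9 and Dmrt3 had been seen. All 12 measured genes have at least 50 UMIs in wild type cells, and 5 of the 15 members stand in a fixed gene list. The 7 measured members outside those lists and the named genes had a median of -0.55.

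Dividing cells of clusters 10 and 16 made up 1.63% of wild type and 7.47% of ShhN cells, and could reflect SHH-driven division, clusters made by library-wide differences, or more germinal zone in the ShhN dissection. Mki67 or Top2a was seen in 14.8% of ShhN and 4.75% of wild type cells of any class at equal depth (16.1% and 5.36% before thinning), a share that does not depend on clusters. Per radial glia-like cell the log2 ratio of cells in clusters 10 and 16 was 1.89 [1.49, 2.29]. This value follows from shares already seen, and radial glia-like cells stand for only part of the germinal zone. It therefore leaves open whether the ShhN dissection held more germinal zone. A first test of that explanation, the share of clusters 4 and 12 (12.5% and 6.69%), was replaced after it was seen, because cluster 3, 88.4% ShhN, may hold the same kind of cell. Condition, library and dissection cannot be told apart in these 2 libraries, and embryos dissected to 1 fixed area and sequenced as separate libraries would separate them.

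Globin and Ttr transcripts were lower in ShhN cells and in ShhN free RNA, where Hbb-bs stood at 10070.5 and 5071 CPM and Ttr at 57.9 and 0 CPM in the wild type and ShhN library.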
